A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

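The series compared wild-type budding yeast (Saccharomyces cerevisiae) exposed for 3 h to Zymolyase 100T at 5 units/ml, an enzyme preparation that digests the glucan of the yeast cell wall, with the untreated part of the same culture. Cells were grown in rich medium at 24 °C, diluted and regrown for 2 h 30 min, and each culture was then split. Per the labels, RNA of 2 cultures was analysed and each was hybridised on a pair of two-colour arrays with the dyes swapped, which gave 4 arrays. Treated RNA carried Cy3 on arrays 1 and 3 and Cy5 on arrays 2 and 4. The labels do not say which arrays share a culture.

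The authors deposited 1 table of values with a row per open reading frame (ORF), which holds log ratios of the 2 channels. The base of the deposited values is not stated, and they were taken as log2 ratios, already normalized by the authors in a way the labels do not describe. Every fold given here rests on that reading of the base. The normalization method, background correction and filters are not given in the sources used here, and neither is the channel in the numerator. Deposited values of arrays with opposite dye orientation correlated below 0 across ORFs (r from -0.54 to -0.09), so the values had not been turned for the dye swap. Signs were turned by the dyes in the labels so that all 4 arrays run the same way. The labels do not settle which way that is. The sign was therefore set so that SLT2, the protein kinase of the cell wall integrity pathway, is positive, a choice made after its values were seen. Each change is given as lying on the side of SLT2 or on the opposite side, with no statement of which side is the higher in treated cells. As background, SLT2 and the genes its pathway controls are known to be induced by cell wall damage; with that knowledge the side of SLT2 would be the higher after Zymolyase, which these data do not settle. Turning every sign the other way swaps the sides and changes no size, count or test. After turning, the median log2 ratio was 0.04, -0.03, -0.05 and -0.04 on arrays 1 to 4.

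The table held 6209 rows, of which 2 were control rows that were left out of the tests. Of the 6207 ORF rows, 5654 matched the RefSeq gene table of assembly R64 by locus tag and took their gene names from it, while 553 did not and kept their systematic names. The build behind the array is not given in the sources used here, so no coordinates are printed. Empty cells made up 18.0%, 21.3%, 20.0% and 16.0% of ORFs on arrays 1 to 4. Values were present on 4 arrays for 4543 ORFs, on 3 for 436, on 2 for 215, on 1 for 246 and on 0 for 767. No intensities were used here, so the signal over background behind a ratio is unknown, and the number of arrays limits the precision. Probe sequences and strand were not used here, so near-identical genes (PHO11 and PHO12, the CUP1 copies, hexose transporters, ribosomal protein pairs) and overlapping ORFs may share signal.

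The main test used limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on ORFs with values on 4 arrays. The arrays of a culture were averaged first, which cancels a dye effect and leaves n = 2 cultures. Both possible pairings (1 with 2 and 3 with 4; 1 with 4 and 2 with 3) were fitted and each gene kept its larger p. The pairing that is not the true one averages across cultures, so its variance does not measure the spread between them. Benjamini-Hochberg adjustment ran over 4543 genes at a threshold of 0.05. Values are the mean ± SD of 4 arrays. Gene lists were written from general knowledge of yeast before the data were examined, 25 in all, and tested with camera at a preset inter-gene correlation of 0.01 in both pairings with the larger p kept; an estimated correlation and fry were alternatives. Another 5 lists were written after the largest changes were seen.

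The genes named were fixed by a rule before the data were examined. It took the 15 largest changes on the positive side and the 10 largest on the negative side among genes past the threshold with 1 sign on all 4 arrays, 18 sentinels, and the 2 highest and 2 lowest members of each list. The positive side of that rule is the side of SLT2. YPS5 and YPS7 stand outside the rule and were named to complete the yapsin list. CHS7, MFA1, PLB2, FAF1, SED1, PGM2, GPP2 and ALD3, the ORFs named as neighbours or tandem pairs (YDL023C, YMR173W-A, DDR48, CIS3, HSP150, DOG1 and DOG2), the genes measured on 3 arrays (PRM10, CRG1, NQM1, PHO12 and YPS6) and the genes of the 5 later lists stand outside the rule and were chosen after their values were seen.

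Alternatives were each pairing alone, all 4 arrays as if independent with and without a dye term, centring, centring with scaling, quantile normalization, ORFs with 3 or more values, robust empirical Bayes, 3 other thresholds and leaving out each array in turn. Fits without 1 array took the remaining arrays as independent with a dye term, so they also changed the unit of replication. Scaling used limma's median absolute value method, since the planned function returned no values on arrays centred at 0. Averaging of several probes per gene did not apply, because each ORF had a single row. In 20 simulations of this comparison over 4543 genes with 200 changed, the test recovered 69.9% of changes of 1.5-fold, 98.9% of 2-fold and 100% of 4-fold. On average 11.1% of its calls were false (1.82% to 23.0%), above the nominal 5%, against 0.293% among calls of at least 2-fold. Of 200 simulated lists with no change, 0 had a camera p under 0.05, and 20 of 20 lists shifted by 0.5 on the log2 scale did. Simulated genes were drawn independently, so these lists do not show how camera behaves on correlated genes. Estimated from 4 arrays, the correlation reached 0.82 in the real histone list. Smaller list shifts were not simulated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.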

Results

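Transcript ratios between wild-type yeast treated for 3 h with Zymolyase and the untreated part of the same cultures were measured on 4 two-colour arrays from 2 cultures, and 4543 ORFs had a value on each array. The comparison asks which transcripts differ when the cell wall is digested. The labels do not give the numerator of the ratios, so changes are described as lying on the side of SLT2 or opposite to it, and positive log2 values mark the side of SLT2. Values are mean log2 ratios ± SD over 4 arrays (n = 2 cultures).

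SLT2, which encodes the mitogen-activated protein kinase of the cell wall integrity pathway, differed between treated and untreated cells by 2.25 ± 0.11. On its side lay 207 of the 270 genes past the test, led by KDX1, which encodes a relative of Slt2 (5.94 ± 3.53), RTC3 (3.76 ± 0.61), YPL088W (3.64 ± 0.86) and HSP12, which encodes a small stress protein of membranes (3.49 ± 1.67). The opposite side held 63 genes, led by APE1, a vacuolar aminopeptidase (-1.63 ± 0.60), and YHB1, a nitric oxide-detoxifying flavohaemoglobin (-1.48 ± 0.26). Changes of at least 2-fold numbered 73 on the side of SLT2 and 9 on the other, and 45 and 2 ORFs reached 2-fold on each array, the latter being APE1 and YHB1.

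The other large changes on the side of SLT2 were NFG1 (3.38 ± 0.64), the yapsin protease gene YPS3 (3.26 ± 1.66), YOL053C-A (3.10 ± 0.90), the wall mannoprotein gene CWP1 (3.04 ± 0.54), NCW2 (2.79 ± 0.54), PRM5 (2.56 ± 0.53), AFR1 (2.40 ± 0.36), PPR1, a regulator of pyrimidine synthesis (2.36 ± 0.21), the wall protein gene PIR3 (2.21 ± 0.68) and GPD1, which encodes an enzyme of glycerol synthesis (2.20 ± 0.22). YOL053C-A had no entry in the gene table. KDX1 ranged from 3.18 on array 1 to 10.72 on array 4, and a fit to 3 arrays that weighs both dye orientations equally gave 4.89 without array 4 and 7.0 without array 2. The same fit gave HSP12 2.76 without array 2 and 4.22 without array 4. With robust empirical Bayes in limma the adjusted p was 0.370 for KDX1, 0.352 for HSP12 and 0.287 for YPS3, and without array 1 it was 0.0524 for KDX1 and 0.0598 for HSP12, which also missed the threshold without array 3 (0.0664).

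**Figure D1:**
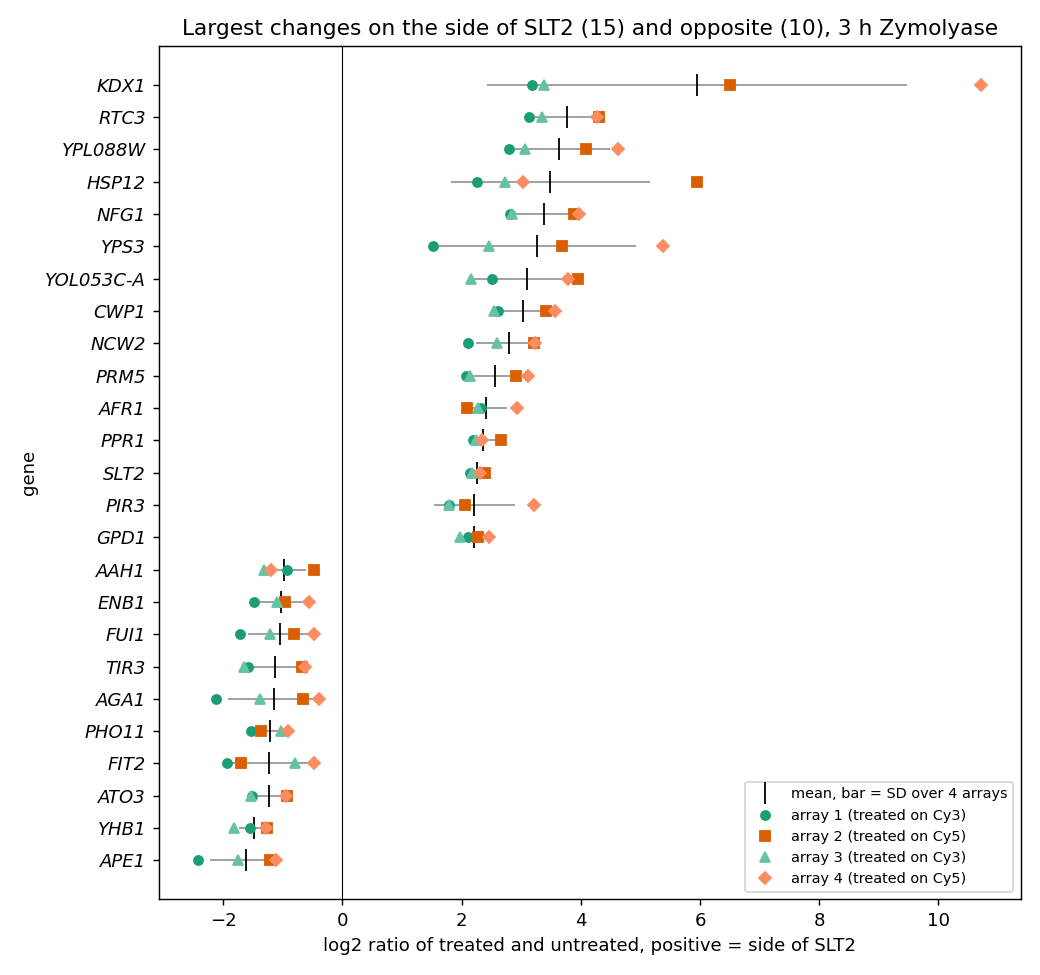
Log2 ratio of treated and untreated RNA (x axis, positive on the side of SLT2) for the 15 largest changes on that side and the 10 largest opposite; symbols are single arrays, ticks the mean and bars the SD over 4 arrays. KDX1 spreads from 3.18 to 10.72, while the 4 values of SLT2 lie close to their mean of 2.25.

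Genes known as targets of Slt2 and its transcription factor Rlm1 moved together with SLT2, itself a member of the list. Of 20 measured members 18 changed on its side and 0 opposite, with a median of 1.61, and 18 did so adjusted over the list alone. PST1 (2.09 ± 0.57), CRH1, a glucan-chitin crosslinking enzyme gene (1.64 ± 0.28), PIR1 (1.04 ± 0.03), RLM1 itself (1.09 ± 0.45) and YPS1 (0.82 ± 0.50) were among them. The 2 members that did not pass were GSC2, also called FKS2, with 0.18 ± 0.83 and CHS3 with -0.05 ± 0.28. With treated RNA on Cy3, GSC2 had 0.61 on array 1 and 1.08 on array 3. With treated RNA on Cy5 it had -0.17 on array 2 and -0.79 on array 4. Its mean therefore averages opposite signs by dye and does not show that GSC2 was unchanged. The list passed camera (adjusted p = 4.53e-25) and had adjusted p = 0.504 with an estimated correlation. RLM1 no longer passed with arrays centred (adjusted p = 0.0573 in limma), and neither did YPS1 (adjusted p = 0.105).

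Other wall genes divided by group. Structural wall proteins had 9 of 22 members on the side of SLT2, CWP1, NCW2 and SED1 (2.06 ± 0.50) among them, and 3 opposite, namely TIR3 (-1.13 ± 0.56), FIT2 (-1.23 ± 0.70) and PLB2 (-0.89 ± 0.59). FIT2 is known for holding siderophore-bound iron at the wall. Adjusted over the list alone the counts were 13 and 6. Glucan synthesis and remodelling had 6 of 21 on the side of SLT2 and 0 opposite (11 and 2 adjusted over the list alone), with CRH1 and EXG1 (1.16 ± 0.12) highest, while UTR2 had -0.51 ± 0.36, SCW10 -0.41 ± 0.34 and the glucan synthase gene FKS1 0.60 ± 0.42, none past the test. Of 10 chitin synthesis genes 3 changed on the side of SLT2, GFA1 (1.54 ± 0.07), CHS1 (0.87 ± 0.16) and CHS7 (0.86 ± 0.09), and 6 did adjusted over the list alone. CHS2 had -0.09 ± 0.22. The list of yapsin proteases also holds BAR1, the gene of a related protease that is not a yapsin. It had 2 of 4 measured members on the side of SLT2, YPS3 and YPS1, with MKC7 at -0.28 ± 0.15 and BAR1 at 0.05 ± 0.14. YPS6, with values on arrays 1, 2 and 3 only (1.17, 1.96 and 1.23), did not enter the test. Neither did YPS5, with mixed signs on 3 arrays (0.16, -0.20 and 0.83), nor YPS7, with a value on 1 array (-0.38). The call of this list ended with arrays centred (adjusted p = 0.140) and in 6 other settings. In pathway signalling 6 of 20 genes changed on the side of SLT2, PTP2 (1.13 ± 0.05) among them, 7 adjusted over the list alone, with SWI4 at -0.35 ± 0.09 and LRG1 at -0.30 ± 0.35 not past the test. These 5 lists passed camera, and each had adjusted p = 0.504 with an estimated correlation. At the preset correlation the signalling call ended with centring and scaling (adjusted p = 0.0580) and without array 3 (0.0613). PLB2 no longer passed with arrays centred (adjusted p = 0.0589 in limma). The Rlm1 and Slt2 target list shares 8 measured genes with structural proteins, 4 with signalling, 3 with glucan, 2 with yapsins and 1 with chitin.

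Some lists of stress genes lay in part on the side of SLT2, whereas the chaperones had a negative median. Osmotic stress targets had 12 of 14 members there and 0 opposite (12 adjusted over the list alone, median 0.90), including GPP2, which acts with GPD1 in glycerol synthesis (1.63 ± 0.14), and ALD3 (1.51 ± 0.25), while GLR1 (0.13 ± 0.22) and ENA1 (0.00 ± 0.24) did not pass. The HOG pathway genes themselves had 0 of 17 past the test in limma, with 1 at an unadjusted p under 0.05, but 4 on the side of SLT2 and 2 opposite with arrays 1 and 4 and arrays 2 and 3 as the cultures. HOG1 had 0.37 ± 0.39 and OPY2 0.39 ± 0.73. Targets of the general stress factors Msn2 and Msn4 had 14 of 26 members on the side of SLT2 and 0 opposite (18 and 1 adjusted over the list alone, median 0.72), and shared 3 measured genes with the osmotic list. GND2 (-0.13 ± 0.28) and SSA4 (-0.35 ± 0.28) were its lowest. Trehalose and glycogen metabolism had 6 of 15 on that side and 0 opposite (7 adjusted over the list alone), TSL1 (1.23 ± 0.30) and PGM2 (1.09 ± 0.15) among them, while TPS2 had 1.21 ± 1.31. The count was 3 without array 1 and also without array 3, and 4 with arrays centred. The osmotic target, Msn2 and Msn4 and trehalose lists passed camera, each with adjusted p = 0.504 with an estimated correlation. The sentinel CTT1, a catalase gene, had values on arrays 1, 2 and 3 only (1.25, 3.99 and 1.31), and STL1 on array 2 only (0.10), so neither entered the main test.

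Lists of growth and mating genes had negative medians. Of 41 ribosome biogenesis genes 3 changed opposite to SLT2, YTM1 (-0.58 ± 0.09), HAS1 (-0.54 ± 0.24) and FAF1 (-0.54 ± 0.22), and 28 did adjusted over the list alone. All 41 means were negative, with a median of -0.39. The count of 3 depended on the setting. It was 0 with arrays centred, and 1 without array 2, without array 3 and without array 4. It was 5 with quantile normalization, 20 for 4 arrays as if independent with a dye term, 24 with robust empirical Bayes, and 32 with arrays 1 and 4 and arrays 2 and 3 as the cultures. Of 129 cytosolic ribosomal protein genes 0 passed in limma, with 1 at an unadjusted p under 0.05; their median was -0.12, and 0.12 on array 1. RPS21A had -0.31 ± 0.20. Of 17 pheromone response genes 3 changed opposite to SLT2, the agglutinin genes AGA1 (-1.14 ± 0.77) and AGA2 (-0.74 ± 0.17) and MFA1 (-0.54 ± 0.33). Histone genes had 0 of 10 past the test in limma, 1 at an unadjusted p under 0.05, and a median of -0.18. Their array medians followed the dyes. These were 0.32 and -0.025 on arrays 1 and 3, with treated RNA on Cy3, and -0.38 and -0.63 on arrays 2 and 4, with it on Cy5. Chaperones had a median of -0.19 with 1 of 25 members past the test, SSE2, on the side of SLT2 (0.92 ± 0.13), and HSP82 at -0.55 ± 0.71. HSP82 also split by dye, with 0.16 and -0.14 on arrays 1 and 3 and -0.77 and -1.44 on arrays 2 and 4. All 5 lists passed camera. With an estimated correlation the adjusted p was 0.504 for ribosome biogenesis, pheromone response and chaperones and 0.757 for ribosomal proteins and histones. At the preset correlation the histone call ended without array 3 (adjusted p = 0.208), without array 4 (0.212) and with the 4 arrays as if independent and no dye term (0.0790), and the chaperone call without array 1 (0.0790) and without array 2 (0.0671). Adjusted over the list alone, 3 pheromone genes, 0 ribosomal protein genes and 0 histone genes lay opposite to SLT2, and 2 chaperone genes lay on its side and 1 opposite. MFA1 no longer passed with arrays centred (adjusted p = 0.0689 in limma). With arrays 1 and 4 and arrays 2 and 3 as the cultures, 7 pheromone, 5 ribosomal protein, 3 histone and 8 chaperone genes lay opposite to SLT2, and 2 chaperone genes on its side.

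Further genes opposite to SLT2 among the 10 largest were the ammonium exporter gene ATO3 (-1.23 ± 0.34), the acid phosphatase gene PHO11 (-1.21 ± 0.29), the uridine permease gene FUI1 (-1.05 ± 0.54), the siderophore transporter gene ENB1 (-1.03 ± 0.38) and the adenine deaminase gene AAH1 (-0.98 ± 0.37). FIT2 no longer passed with arrays centred (adjusted p = 0.102 in limma), nor AAH1 with arrays scaled (0.0628), nor AGA1 with the 4 arrays as if independent and no dye term (0.0557).

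Small shifts marked the remaining lists that passed camera on the side of SLT2. Citrate cycle and respiration had 2 of 37 members past the test, IDH2 (0.62 ± 0.22) and IDH1 (0.54 ± 0.12), oxidative stress 2 of 18, GTT1 (0.69 ± 0.18) and MCR1 (0.52 ± 0.19), and G1 and S phase 2 of 20, SVS1 (0.94 ± 0.06) and PCL2 (0.78 ± 0.04). These 3 lists had adjusted p = 0.757 with an estimated correlation. Calcineurin targets had 2 of 13, YPS1 and CMP2 (0.71 ± 0.28). That count was 1 with arrays centred and without array 1, 3 or 4, and 3 without array 2. The unfolded protein response had 0 of 16 in limma, with 3 at an unadjusted p under 0.05 and PDI1 at 0.43 ± 0.30. It had 3 past the test for 4 arrays as if independent with a dye term, and 2 with robust empirical Bayes. Both lists had adjusted p = 0.504 with an estimated correlation. At the preset correlation the calcineurin call ended without array 3 (adjusted p = 0.228), that of the unfolded protein response without array 4 (0.0537), and those of oxidative stress (0.0734) and of G1 and S phase (0.0671) without array 2. Adjusted over the list alone, 6, 2, 2, 3 and 0 members of these 5 lists lay on the side of SLT2. With arrays centred IDH1, IDH2 and MCR1 no longer passed in limma (adjusted p = 0.0537, 0.0617 and 0.0606), nor without array 1 (0.0611, 0.0807 and 0.0611) or array 2 (0.116, 0.0979 and 0.112), which left 0 citrate cycle genes. With arrays 1 and 4 and arrays 2 and 3 as the cultures the counts on the side of SLT2 and opposite were 13 and 1 for citrate cycle and respiration, 7 and 1 for oxidative stress, 5 and 1 for G1 and S phase, 4 and 0 for calcineurin targets and 5 and 1 for the unfolded protein response.

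Not past camera were the HOG signalling genes and 5 more lists. Glycolysis had 1 of 24 past the test, HXK1 (0.77 ± 0.14), and hexose transport 1 of 11, HXT1 (1.84 ± 0.40). Daughter cell separation had PIR1 on the side of SLT2 and SUN4 opposite (-0.60 ± 0.31) of 13. SUN4 narrowly missed the threshold with arrays scaled (adjusted p = 0.053 in limma) and without array 2. It also missed it with the 4 arrays as if independent and no dye term (adjusted p = 0.0501 in limma). G2 and M phase had 0 of 15 in limma, 0 at an unadjusted p under 0.05, and meiosis, a list of another cell state, 0 of 3, with 1 at an unadjusted p under 0.05. For glycolysis, hexose transport and G2 and M phase the medians (-0.01, -0.07 and -0.01) had the opposite sign to the camera direction, and those of glycolysis and of G2 and M phase turned positive with arrays centred. Adjusted over the list alone, 2 glycolysis genes, 1 hexose transport gene and 2 daughter cell separation genes lay on the side of SLT2 and 1 of the last list opposite, with 0 for the HOG, G2 and M phase and meiosis lists. With arrays 1 and 4 and arrays 2 and 3 as the cultures, 2 genes of G2 and M phase and 1 of meiosis lay on the side of SLT2.

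**Figure D2:**
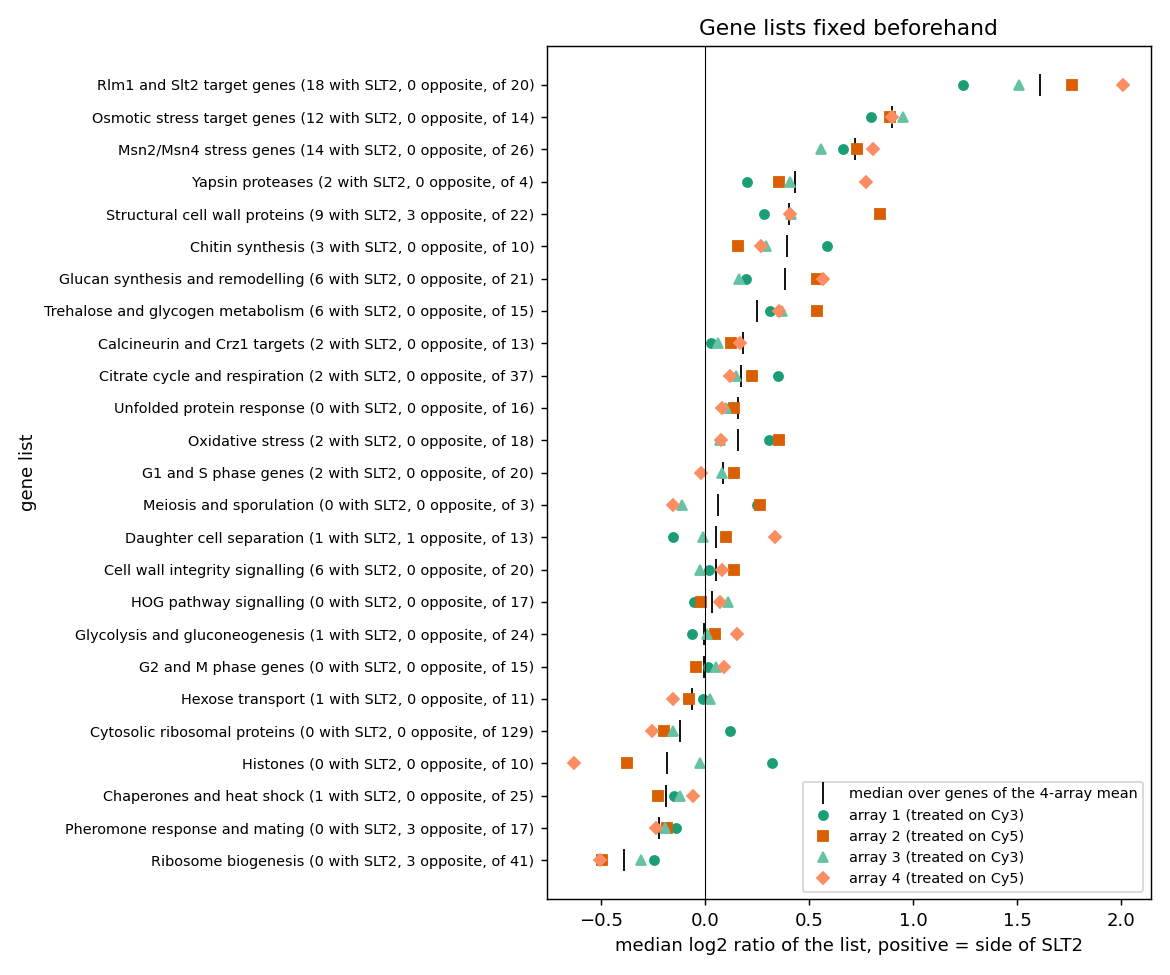
Median log2 ratio of each of 25 gene lists (y axis), positive on the side of SLT2; symbols are the medians on single arrays and ticks the median over genes of the 4-array mean. Rlm1 and Slt2 targets stand at 1.61 and ribosome biogenesis at -0.39, and histones range from -0.63 to 0.32 across arrays.

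Arrays 2 and 4 were the most alike (r = 0.75 across genes, which are not independent replicates) and arrays 1 and 4 the least (r = 0.09, Spearman's rho -0.09). The count opposite to SLT2 was 27 with arrays centred and 19 with centring and scaling, against 63. It was 39 without array 2 and also without array 4, against 193 for 4 arrays in the same kind of fit. The share of calls on the side of SLT2 was 76.7% as deposited, 86.0% after centring and 88.6% after scaling as well. It was 62.3% for 4 arrays as if independent with a dye term, 61.4% with robust empirical Bayes and 48.7% with arrays 1 and 4 and arrays 2 and 3 as the cultures. Of 25 lists 19 passed camera with the preset correlation. With a correlation estimated from the culture averages 0 passed and 0 had an unadjusted p under 0.05, with one estimated from 4 arrays 0 passed and 5 did (lowest adjusted p = 0.177), and by fry 0 passed and 8 did. An estimated correlation also makes camera use the few residual degrees of freedom. A list that missed the threshold there is therefore not shown to be unchanged. Estimated from 4 arrays, the correlation was -0.070 for osmotic targets, -0.037 for Msn2 and Msn4 and -0.063 for trehalose, below the preset 0.01. A larger correlation is thus argued against as the cause for these lists in that setting. The same holds for signalling (-0.047), glucan (-0.042), chaperones (-0.020), pheromone response (-0.0040), calcineurin targets (-0.0031), yapsins (0.0066) and the unfolded protein response (0.0087). Estimates of the other called lists ran from 0.043 for structural wall proteins up to 0.82 for histones, and the cause of their lost calls was not tested.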

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

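The tests of dye orientation, neighbouring ORFs and array orientations were all chosen after the results they bear on were seen.

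One array stood far from the other 3 for 4 of the genes named. SSE2 had 1.12 on array 1 and 0.85 to 0.88 elsewhere. RPS26A had 0.52 on array 1 and -0.17 to -0.12 elsewhere. SSA4 had 0.07 on array 3 and -0.51 to -0.45 elsewhere. HTZ1 had -0.84 on array 4 and -0.29 to -0.20 elsewhere. Chance marks about 1 in 20 groups of 4 values in this way, and 132 genes and 25 lists were checked, so these 4 are no more than chance would give.

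The 4 arrays can be turned in 8 ways if turning all of them together is ignored, and 1 of these, the real one, gave as many as 270 genes in limma; the highest of the others was 0. At an unadjusted p under 0.05 the real orientation gave 878 genes, and the one that turns arrays 2 and 4 alone, which follows the dyes, gave 599. With 8 orientations no share under 0.05 can be reached.

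Changes on the side of SLT2 were larger where treated RNA carried Cy5 in 139 of 207 genes (exact binomial p = 9.03e-07, two-sided). The same held for 18 of the 19 of at least 4-fold. This test and the one below take genes that share the same 4 arrays as independent, so p does not measure the spread between arrays. A dye shift of one size for all genes was not left in the deposited values. It would also sit in the 4273 genes not called, whose median half-difference between orientations was -0.00035. The median was 0.08 for the genes on the side of SLT2, 0.10 for those opposite and 0.45 for the 19 genes of at least 4-fold. Array medians were near 0 as deposited, which holds the median of the genes not called near 0 whatever the shift was. That median is therefore no test of a shift before deposit. If centring before deposit took such a shift out, it did so for called genes as well. A dye shift that differs between genes is not addressed by these values. Compression of every ratio on the arrays with treated RNA on Cy3 is argued against for the called genes opposite to SLT2. Of these, 19 of 63 were larger with treated RNA on Cy5. A candidate explanation that stays open is an unequal signal floor of the dyes. Under such a floor the 2 sides would be larger in opposite orientations, as the called genes were. Of the 63 genes opposite to SLT2, 44 were larger with treated RNA on Cy3 (exact binomial p = 0.00223). Whole lists with negative medians did not all follow the called genes. The medians of ribosome biogenesis were -0.25 and -0.31 with treated RNA on Cy3 and -0.50 and -0.51 on Cy5, which such a floor does not predict. Those of amino acid synthesis, a list written later, were -0.29 and -0.33 on Cy3 and -0.05 and -0.14 on Cy5. No intensities were used to test the signal floor directly, and no biological explanation was tested.

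Genes on the side of SLT2 often stood at neighbouring ORF numbers. Of the 7 without an entry in the gene table, 5 had such a neighbour, against 38 of 200 with an entry (Fisher's exact p = 0.00477, two-sided), for example YDL023C (1.96) beside GPD1 and YMR173W-A (1.90) beside DDR48; shared sequence may account for these ORFs, but probe sequences were not used here. Among genes with an entry, 34 had a neighbour on their side, against a mean of 13.2 in 10000 shuffles of the calls (one-sided permutation p = 1e-04, the smallest these shuffles can give), which argues against chance placement. Without the tandem pairs PIR1 and PIR3, CIS3 and HSP150, YPS1 and YPS3, and DOG1 and DOG2, 26 did, against a mean of 12.1 (one-sided permutation p = 0.0058), so these 4 pairs were not the whole cause. The pairs were picked by eye after the neighbours were listed, sequence likeness was not measured, and no biological explanation was tested.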

How the results depend on the processing

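The settings with only ORFs of the gene table and with a list correlation estimated from 4 arrays were chosen after seeing the data. None of the 270 genes past the main test changed sign in any of the 14 refits that tested it. Refits that keep the 4-array mean could not turn a sign. Nor could leaving out an array for the 205 of 207 and 63 of 63 with 1 sign throughout. Calls did end. Of the 270, 104 were lost with centring and scaling, 77 with centring, 38 with quantile normalization and 55 to 92 without 1 array. Fits without 1 array took arrays as independent with a dye term. With all 4 arrays that kind of fit called 512 genes and lost 3 of the 270. Most of the 69 called genes followed here came from the naming rule, which favours large changes. Of these 69, 49 passed in every refit that tested them. The 20 that did not were AAH1, AGA1, FAF1, FCY2, FIT2, HAS1, HSP12, IDH1, IDH2, KDX1, MCR1, MFA1, PHO3, PLB2, RLM1, SUN4, YPS1, YPS3, YTM1 and ZRT2. The ratio's base and direction, the signal over background and the pairing of arrays are not known, and they limit every value. The array numbers in the labels do not say which arrays share a culture, so both possible pairings were fitted and none was chosen.

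Counts are given as the side of SLT2 and the opposite side, against 207 and 63. The pairing that is not the true one averages across cultures and may understate the spread between them. Counts were 598 and 631 with arrays 1 and 4 and arrays 2 and 3 as the cultures, against the same 207 and 63 with the other pairing. They were 319 and 193 for 4 arrays as if independent with a dye term, 338 and 189 for arrays as if independent with a dye term and ORFs of 3 or more values, which changes 2 choices at once, and 358 and 225 with robust empirical Bayes. The opposite count was 27 with arrays centred and 19 with scaling as well, and 153 at an adjusted p under 0.10. A 2-fold minimum left 73 and 9, and 2-fold on each array without a test gave 45 and 2. The count of lists past the threshold, 19, was 0 with an estimated correlation, 0 with one estimated from 4 arrays and 0 by fry. Leaving out 1 array in turn gave 151 to 196, 39 to 60 and 15 to 17 lists; the 39 came without array 2 and also without array 4. These fits took arrays as independent with a dye term, so their counterpart with 4 arrays is 319 and 193 with 18 lists. With 3 arrays, both dye orientations weigh equally in the fit, and the lone array of one is assumed to vary like the others. The cause was not tested for any of these, apart from the smaller number of arrays or genes that a setting itself imposes. List correlation was weighed above only for the osmotic, Msn2 and Msn4 and trehalose lists. With the preset correlation, 8 of the 19 called lists missed the threshold in at least 1 refit: the yapsins in 7, and signalling, calcineurin targets, the unfolded protein response, oxidative stress, chaperones, histones, and G1 and S phase.

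Among the 132 genes and 25 lists followed, signs turned only for those that were not past the test, in 27 gene values, none past the threshold. With arrays centred the list medians of glycolysis and of G2 and M phase were 0.014 and 0.013, and with scaling 0.016 and 0.0055. GSY1 was 0.012 with scaling, and HAC1 0.12 with quantile normalization. Without 1 array in turn the values ran from -0.093 to 0.039 for GSY1, -1.61 to 1.26 for HAC1, -0.13 to 0.019 for CHS3, -0.22 to 0.031 for CHS2, -0.013 to 0.79 for OPY2, -0.13 to 0.13 for ENA1, -0.059 to 0.11 for FAR1, -0.34 to 0.0057 for GPX2, -0.11 to 0.017 for NOP58, -0.16 to 0.025 for NUG1, -0.081 to 0.15 for RPS15 and -0.14 to 0.18 for RPS26A. They ran from -0.055 to 0.17 for DMC1, -0.16 to 0.11 for HHT2, -0.091 to 0.029 for HHT1 and -0.32 to 0.010 for CLB1. List medians ran from -0.032 to 0.029 for glycolysis, -0.011 to 0.083 for G2 and M phase, -0.055 to 0.17 for meiosis, -0.085 to 0.038 for hexose transport, -0.11 to 0.11 for daughter cell separation and -0.013 to 0.088 for HOG signalling. The cause was not tested.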

Other observations

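The lists of this part and every test on them were chosen after the largest changes were seen, so their counts are hypotheses about these groups and not independent evidence.

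Genes of nutrient uptake and synthesis were among the changes opposite to SLT2. Of 18 purine synthesis and salvage genes 2 changed opposite, AAH1 and the purine-cytosine permease gene FCY2 (-0.66 ± 0.18), with a list median of -0.40, and neither passed with arrays scaled (adjusted p = 0.0628 and 0.0614 in limma). Of 12 phosphate acquisition genes 3 did, the acid phosphatase genes PHO11, PHO5 (-0.83 ± 0.17) and PHO3 (-0.81 ± 0.39), whose like sequences can share signal; PHO3 no longer passed with arrays scaled (adjusted p = 0.0752 in limma). Of 41 amino acid synthesis genes 7 did, with HIS4 (-0.75 ± 0.24) and GLN1 (-0.74 ± 0.23) largest. These 3 lists passed camera, each with adjusted p = 0.333 with an estimated correlation. Of 12 zinc and copper genes 3 changed opposite, the zinc transporter genes ZRT1 (-0.68 ± 0.32) and ZRT2 (-0.65 ± 0.50) and CUP1-2 (-0.66 ± 0.37), and the list did not pass camera (adjusted p = 0.111). ZRT2 missed the threshold with arrays scaled (adjusted p = 0.0646 in limma).

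Iron uptake genes had 2 of 17 members opposite to SLT2, FIT2 and ENB1, and 1 on its side, the haem oxygenase gene HMX1 (0.74 ± 0.25); the list passed camera with adjusted p = 0.457 with an estimated correlation. Its members were more negative on arrays 1 and 2 than on arrays 3 and 4 for 13 of 17 genes, with a median contrast of -0.597 (SD 0.81, SE 0.197 over genes), and 0 of 10000 random lists of the same size were as low; random lists ignore the correlation among iron genes. A dye effect of one size on arrays of the same orientation is argued against, because each side of the contrast holds an array of either orientation and such an effect cancels; one that differs between arrays is not. A difference between the cultures may be the source, but the labels do not say which arrays share a culture, so it cannot be told apart from a difference between arrays.

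Of genes measured on 3 arrays, 8 were at least 2-fold on each of them on the side of SLT2 and 1 opposite, PHO12 (-1.49, -1.24 and -1.06 on arrays 1, 2 and 4). On arrays 1, 2 and 3, PRM10 (2.69, 6.54 and 2.36), CRG1 (2.47, 5.07 and 2.61) and NQM1 (2.51, 4.01 and 2.54) were largest. For these genes array 2 held the highest value and was the only array with treated RNA on Cy5.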
